A study of Mus musculus with 2 samples.

How the data were processed

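H3K36me3 ChIP-seq was done on unstimulated bone marrow-derived macrophages of C57BL/6J mice. Per the labels, each library started from 10 ng of DNA with a fragment size range of 350 to 480 bp, and the files use the mm10 assembly. The 2 samples are biological replicates 1 and 2 of 1 group, so no comparison between groups was made and no test across samples was possible. The labels also name a control experiment, which was not analysed here. They give the sex of the animals as not collected.

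The authors deposited 4 peak lists: 1 for each replicate, called on that replicate's own alignments and kept when found in pseudoreplicates (random splits of its reads), a pooled list called the same way on both replicates together, and a list of replicated peaks from both. The aligner, the caller and their versions are not given in the sources used here. Each deposited peak has a display score, which in all 4 lists equals 10 times its −log10 p rounded down, with 0 exceptions. The deposited enrichment per peak is a ratio over the background that the authors' caller used. The deposited −log10 p and −log10 q are also the authors' values. These values were used to describe, rank or filter peaks within a list, and the enrichment also to weight a density per gene. That density was averaged over the replicates, whose median enrichments differ (3.22 in replicate 1 and 3.83 in replicate 2), so its ranking leans on replicate 2. The lists hold no read counts, so the depth of each replicate is unknown, and no value carries a counting interval for reads. The number and length of peaks move with depth and with the strength of the immunoprecipitation, which limits every comparison between the replicates.

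Genes were taken from GENCODE release M21 (GRCm38, the same assembly as mm10), with a gene body running from the annotated start to the annotated end over all transcripts. Of records sharing a symbol the longest was used. For each of 21938 protein-coding genes, the percent of the gene body under peaks was computed in each replicate, and a gene was called marked at 20% or more in both. Exons are the union over transcripts of coding genes, and introns the rest of their bodies. Profiles used marked genes of at least 5 kb, with 10 bins along the body and 500 bp bins over 5 kb on either side. A peak counted as shared when 1 peak of the other list covered at least 50% of its length. Chance levels came from 1000 circular shifts of a list within each chromosome. GC content was computed from the GRCm38.p6 sequence.

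The 24 gene lists were fixed before the data were examined: macrophage identity, housekeeping, Toll-like receptor and NF-κB signalling, primary and secondary LPS response, interferon-stimulated, lysosome and phagosome, oxidative phosphorylation, splicing, H3K36 writers, readers and erasers, T cell, B cell, neutrophil, dendritic cell, fibroblast, erythroid and megakaryocyte, neuron, hepatocyte, cell cycle, X inactivation and Y-linked, Zfp-named, olfactory receptor, histone and ribosomal protein genes. The last 4 were drawn by name pattern. Of the symbols listed, 3 had no protein-coding record (Clec7a, Mx2 and Xist). Each list's median covered percent (mean of the replicates) was placed among 10000 random lists of the same size matched on gene length in 20 bins, which describes these libraries and gives no p-value. Since many lists have a median of 0, where ties place them near the 50th percentile, the number of members at 20% was also placed among such lists, a step added after seeing the data. The report gives these ranges as the central 95% of the random lists. Intervals of shares of genes are exact Clopper-Pearson 95% intervals.

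The rule for named genes, also fixed beforehand, took from each list the 3 members with the highest and the 2 with the lowest covered percent (mean of the replicates, ties by symbol). For the macrophage identity and Toll-like receptor lists it took 6 and 4. It also took the 10 coding genes of at least 5 kb with the highest density (enrichment times covered bases, per base of gene body), the 5 with the largest difference between replicates in each direction, and the gene at the top peak of each deposited list. Some genes that the rule takes are not reported here. Genes named outside this rule are said to be so, or are the members behind a count of 5 or fewer. The chosen alternatives were a −log10 q of at least 5, an enrichment of at least 3, other overlap rules, lists of equal length, the authors' combined lists, marking from 10% or 50%, each replicate alone, other gene sets and matching on GC content in 5 bins. Alternatives added after seeing the data were the mean in place of the median, genes with a peak only, leaving out the X and Y chromosomes, overlap summed over peaks, the number of members at 20%, and smaller sets of X-linked genes known to escape inactivation.

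Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1. The steps were tested on simulated data. Of 200 genes simulated at 40% coverage in a single list all 200 reached 20%, and of 200 at 10% coverage 0 did, with a largest error of 0 percentage points. This reads planted intervals back and tests the arithmetic only. All 180 simulated peaks shifted by 25% of their length were found shared. Of 20 lists drawn from genes with a mean coverage of at least 20%, 20 reached the 95th percentile, as did 11 of 200 unrelated lists. The unrelated lists were scored on simulated normal values without ties. Their share therefore does not calibrate percentiles of the real covered percents, many of which are 0.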

Results

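Trimethylation of histone H3 at lysine 36 (H3K36me3) is deposited along the bodies of transcribed genes, mainly by the methyltransferase Setd2 travelling with elongating RNA polymerase II. It was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in macrophages grown from C57BL/6J mouse bone marrow (bone marrow-derived macrophages, BMDM) that received no stimulus. The series held 1 group of 2 biological replicates, listed in the labels as separate biosamples under a single donor record, so the spread between them may be technical. Values are therefore given for each replicate, and the comparisons are between the replicates and between genes or groups of genes within these cells. Read totals were not used here and the depth of each replicate is unknown, so a gene without a peak was undetected in that list, not shown to lack the mark.

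Which regions carried H3K36me3, and did the replicates place it alike? The peak of highest enrichment in replicate 2 lay in Cd84, a receptor of immune cells, at chromosome 1, 171881081 to 171887981 (mm10), with an enrichment of 10.8 as given by the authors. It lay wholly inside the gene and was almost entirely intronic, with 3.30% of its bases in exons. In replicate 1 the highest value, 6.78, belonged to a peak inside Plec, which encodes the cytoskeletal linker plectin, at chromosome 15, 76172519 to 76175329, and that peak was entirely exonic. In the authors' pooled and replicated lists the top peak, at 9.07, was at Zfp263, a zinc finger gene, on chromosome 16 from 3746104 to 3752462. It covered the 3′ end of the gene and ran past it, with 73.7% of its bases inside the gene and 41.8% in exons. Replicate 1 held 32098 peaks over 28.5 Mb, with a median length of 743 bp. Replicate 2 held 58505 peaks over 79.4 Mb, with a median length of 987 bp. The authors' pooled list held 61439 peaks over 90.2 Mb and their replicated list 56117 over 85.9 Mb. Of the replicated peaks, 40.0% touched a replicate 1 peak and 71.9% a replicate 2 peak. That list is thus not the set of peaks called in both replicates.

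Most of what was called in replicate 1 was also called in replicate 2, but not the other way round. Of the replicate 1 peaks, 82.2% had at least 50% of their length under a replicate 2 peak, against a mean of 3.32% after 1000 circular shifts of the peaks within chromosomes. Of the replicate 2 peaks, 16.7% were shared by the same rule, against 0.965%. By bases, 85.2% of replicate 1 lay inside replicate 2 and 30.6% of replicate 2 inside replicate 1. The Jaccard index of covered bases was 29.1%, against 0.930% after shifting, and none of the 1000 shifts (0) reached any of these 3 observed values. The 34562 replicate 2 peaks that touched no replicate 1 peak had a median enrichment of 3.65, against 4.34 for the 23943 that did. The share of peaks called common moved by more than 1.5 times with the overlap rule: with 50% of both peaks required, it was 26.0% for replicate 1, and with 1 bp it was 40.9% for replicate 2.

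H3K36me3 was almost confined to the bodies of protein-coding genes. In replicate 1, 97.8% of peak bases lay in coding gene bodies and in replicate 2, 97.0%, although these bodies make up 39.3% of the genome, a 2.49-fold and a 2.47-fold excess. Shifted peaks reached a mean of 42.1% in each replicate and in 0 of 1000 shifts the observed share. Introns held 71.2% of the peak bases in replicate 1 and 73.2% in replicate 2, and exons 26.5% and 23.8%, where exons make up 3.63% of the genome. Within marked genes, as defined next, exon bases were covered more often than intron bases, at 38.8% against 28.0% in replicate 1 and 67.3% against 55.7% in replicate 2. Exons and introns were not matched on their position along the gene, with which coverage also changed, so this does not show a preference for exons. Sequence with no annotated gene and more than 5 kb from any coding gene, which is 49.4% of the genome, held 0.177% and 0.182% of the peak bases. The 5 kb upstream of coding genes held 0.0586% and 0.0671%, and the 5 kb downstream 1.60% and 2.39%.

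A gene was called marked when peaks covered at least 20% of its body in both replicates. By this rule 1673 of 21938 coding genes (7.63%) were marked, among them Ctss, Rela and Prpf8, while 13457 genes, among them Alb, Cd2 and Gad1, had no peak in either replicate. Of these examples Gad1, the GABA-synthesising enzyme of neurons, was picked after its value was seen. The count followed replicate 1: 1679 genes reached 20% there, 5119 did in replicate 2, and 5271 did in the authors' replicated list. It also moved with the limits, to 3332 genes from 10% covered and 91 from 50%, and to 1067 with peaks of an enrichment of at least 3 and 317 with a −log10 q of at least 5. Only 6 genes reached 20% in replicate 1 alone, against 3446 in replicate 2 alone, and 2 of the 6 had no peak in replicate 2, Rpl27a (26.8% against 0%) and Prmt6 (23.7% against 0%). In marked genes the median covered share was 29.3% in replicate 1 and 59.1% in replicate 2, and 99.0% of them were covered more in replicate 2. Across the 8481 coding genes with a peak in either replicate, the covered shares correlated with a Pearson r of 0.787 and a Spearman rho of 0.770, where genes are not independent replicates. Among coding genes of at least 5 kb the gap was widest at Gas8 (4.99% against 81.5%), Tmem128 (0% against 76.4%), Scrib (11.9% against 85.3%), Gsdmd, which encodes the pore-forming effector of pyroptosis (0% against 71.1%), and Mybbp1a (14.5% against 84.2%). Gaps in the other direction were smaller in genes of this length, among the largest 12.9% against 0% at Zbed6, 18.0% against 7.44% at Ccna2, 10.0% against 0% at Olfr820 and 8.81% against 0% at Zbtb18. Gas8, Mybbp1a, Zbed6 and Ccna2 overlap another coding gene, so covered bases there may belong to that gene. Very short and very long genes were rarely marked, at 0.693% of genes under 2 kb, 13.0% of those from 10 to 20 kb and 0.301% of those of 200 kb or more. A peak in both replicates was found in 18.4% of genes of 200 kb or more, against 1.13% of genes under 2 kb and 43.5% of those from 50 to 100 kb. The longest genes thus also held a peak less often than genes of middle length.

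Along marked genes the signal lay toward the 3′ end. Over the 1598 marked genes of at least 5 kb, peaks covered 1.16% of the first 10% of the gene body in replicate 1 and 4.23% in replicate 2. Coverage was highest in bin 8 of the 10, at 48.4% and 81.0%, and was 36.8% and 69.0% in the last. The last bin thus exceeded the first 31.8-fold in replicate 1 and 16.3-fold in replicate 2. From the annotated gene start to the nearest peak inside the gene, the median distance was 5.18 kb in replicate 1 and 3.64 kb in replicate 2. Past the gene end, coverage was 17.3% and 43.9% in the first 500 bp bin and 3.18% and 11.2% in the last bin of the 5 kb.

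**Figure D1:**
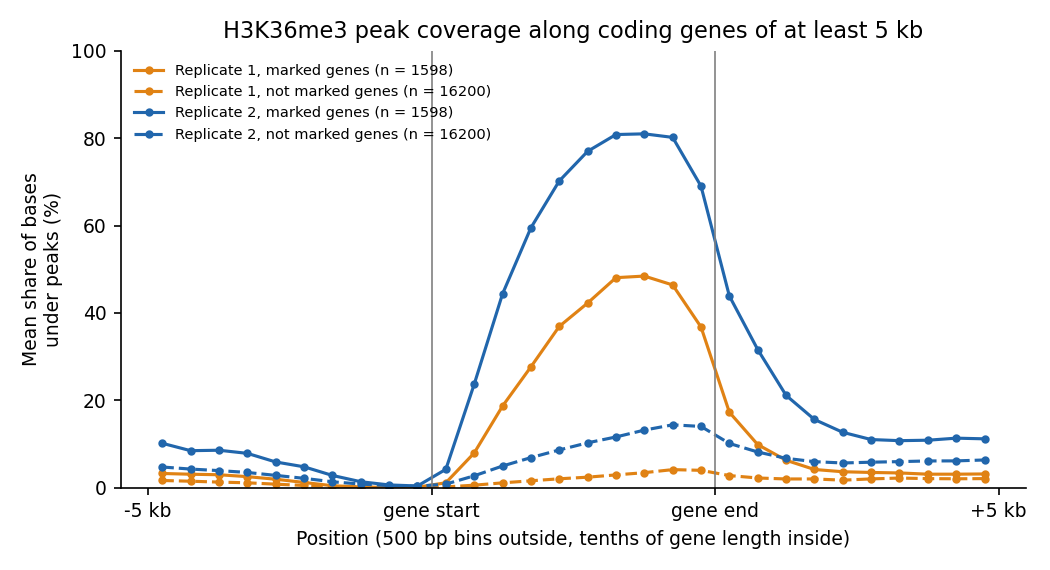
Mean share of bases under H3K36me3 peaks (%) across the 5 kb upstream, the gene body in 10 equal bins and the 5 kb downstream, for marked (solid lines) and other (dashed lines) coding genes of at least 5 kb, with replicate 1 in orange and replicate 2 in blue. In marked genes coverage is highest in bin 8, at 48.4% in replicate 1 and 81.0% in replicate 2.

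Macrophage identity genes were covered more widely than random genes of matched length. Of 39 macrophage identity genes, 15 reached 20% in replicate 1 and 26 in replicate 2, where lists of random genes of matched length gave a central 95% range of 0 to 6 and 4 to 14. Leading members were Ctss, the lysosomal protease cathepsin S (42.8% in replicate 1 and 71.8% in replicate 2), the sialic acid receptor gene Siglec1 (29.8% and 82.6%), the transcription factor gene Irf8 (41.1% and 62.6%), the Fc receptor gene Fcgr1 (34.2% and 67.2%), the phosphatase gene Inpp5d (39.5% and 59.8%) and the lipid-sensing receptor gene Trem2 (37.3% and 60.8%). Ccr2, which marks inflammatory monocytes, and the short genes Cd14, Cebpa and Cebpb had no peak. Of the 10 members shorter than 5 kb, 4 reached 20% in replicate 2. Lysosome and phagosome genes were covered more broadly, with 24 and 35 of 41 members at 20%, against random ranges of 1 to 8 and 7 to 18. The proton pump subunit gene Atp6v0a1 (46.5% and 81.6%) was among the most widely covered, while Atp6ap1, on the X chromosome, and Atp6v0d2 had no peak. The median covered share was 7.00% in replicate 1 and 34.2% in replicate 2 for macrophage identity genes, and 27.8% and 53.5% for lysosome and phagosome genes. Over the mean of the replicates the 2 medians were 20.4% and 39.5%, and each was at the 100th percentile of 10000 random lists.

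Counts for genes of Toll-like receptor and NF-κB signalling lay above those of random genes of matched length, while counts for genes of the response to lipopolysaccharide (LPS, a Toll-like receptor 4 ligand) lay inside the random ranges. Among 41 genes of Toll-like receptor and NF-κB signalling, 11 reached 20% in replicate 1 and 33 in replicate 2, against random ranges of 1 to 8 and 6 to 17. Among genes with a peak only, a comparison chosen after seeing the data, the list's median lay lower, at the 85.5th percentile of random lists. The NF-κB subunit genes Rela (56.0% and 67.6%), Nfkb2 (43.7% and 59.2%) and Relb (27.4% and 63.0%), the kinase genes Tbk1 (43.6% and 71.0%) and Ikbke (22.2% and 74.9%) and the receptor gene Tlr1 (50.4% and 58.2%) led the list. Il1r1 and Nfkbia had no peak, and the X-linked genes Irak1 (0% and 5.11%) and Tlr7 (2.09% and 3.32%) had little. So did the LPS receptor gene Tlr4 (0.542% and 6.05%), which was picked after its values were seen. Of 32 primary response genes to LPS, 1 and 7 reached 20%, led by Cd83 (23.8% and 49.6%), Icam1 (9.31% and 44.9%) and Tnfaip3 (13.1% and 36.4%). The chemokine genes Ccl3 and Ccl4 had no peak. Of 28 secondary response genes, 0 reached 20% in replicate 1 and 3 in replicate 2: Il15 (10.3% and 31.7%), Il27 (0% and 35.0%) and Il10 (0% and 34.2%), while Ccl12 and Ccl2 had no peak. All 4 counts lay inside the random ranges, which for each list were 0 to 5 in replicate 1 and 2 to 10 in replicate 2. Of the primary response genes 18 are shorter than 5 kb, a length at which calls are rare over all coding genes. Such short genes can be called, however. Of 62 ribosomal protein genes shorter than 5 kb, 35 reached 20% in replicate 2, against 3 of these 18. Of the 14 longer primary response genes 4 did. Of the 19 longer secondary response genes 3 did. Nfkbia, Nfkbiz and Tnfaip3 belong to both the signalling and the primary response list.

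Interferon-stimulated genes were covered more widely than any other of the 24 lists in these unstimulated cells. Of 36 members, 29 reached 20% in replicate 1 and 33 in replicate 2, against random ranges of 1 to 8 and 5 to 16, and the median covered share was 36.7% and 67.8%. The antiviral oligoadenylate synthetase gene Oas3 (65.3% and 87.7%) and the antiviral GTPase gene Mx1 (62.1% and 82.0%) were among the highest. Cxcl10 and Isg15, both under 5 kb, had no peak. The list was at the 100th percentile of random lists.

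Among lists of general cell function, the splicing, oxidative phosphorylation, housekeeping and ribosomal protein counts lay above the random ranges in both replicates, the H3K36 count did in replicate 2 only, and the cell cycle counts lay inside. Of 36 splicing genes, 26 and 32 reached 20% (random ranges 1 to 8 and 6 to 16), led by Snrnp200 (58.2% and 88.3%) and Prpf8 (57.7% and 82.8%), core proteins of the spliceosome, and by the RNA helicase gene Ddx17 (52.9% and 75.3%). Srsf2 had no peak and Srsf10 had 0% and 6.43%. Of 35 oxidative phosphorylation genes, 12 and 26 reached 20% (0 to 7 and 4 to 14), led by Sdha (39.3% and 64.6%), Ndufa10 (32.3% and 67.5%) and Ndufv1 (43.3% and 55.4%), while Cox5b and the X-linked Ndufa1 had no peak. Of 32 housekeeping genes, 11 and 23 did (0 to 7 and 4 to 14), led by the elongation factor gene Eef2 (33.8% and 82.6%), Hsp90ab1 (40.9% and 69.1%) and Gusb (32.6% and 76.6%). The annotation holds a second, neighbouring record for Aldoa, at 12.2% and 42.2%, beside the longer record used here, which had no peak; for Atp5o, picked after its values were seen, the record used was at 6.13% and 22.4% and the other at 37.1% and 62.0%. Of 80 ribosomal protein genes, 16 reached 20% in replicate 1 and 49 in replicate 2 (0 to 6 and 5 to 17), led by Rpl6 (39.7% and 73.8%), Rps7 (39.5% and 63.3%) and Rps3 (29.3% and 70.9%), while Rpl10 and Rpl10l had no peak. Both counts were at the 100th percentile of random lists. Their median was 0% in replicate 1, where ties at 0 place it at the 50th percentile, and 26.2% in replicate 2, at the 100th. Among genes with a peak only it lay at the 89.5th, a comparison chosen after seeing the data. Of 30 genes that write, read or erase H3K36 methylation, 5 and 20 reached 20%, led by Glyr1 (41.3% and 76.3%), Brpf1 (42.6% and 70.5%) and the demethylase gene Kdm4a (26.6% and 77.2%), while Dnmt3b and Kdm8 had no peak. In replicate 1 their number lay at the 92.6th percentile of random lists, whose range was 0 to 6, against 4 to 13 in replicate 2. Of 28 cell cycle genes, 2 and 10 reached 20%, inside the random ranges of 0 to 6 and 4 to 13. The replication genes Mcm3 (26.6% and 63.3%), Cdt1 (13.5% and 68.5%) and Mcm6 (12.8% and 46.7%) were highest, and the mitotic genes Aurkb and Birc5 had no peak.

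Markers of other cell types were nearly free of peaks, though a small share of such cells could be present without adding peaks. Of 22 T cell genes 0 reached 20% in either replicate, with Cd28 (12.5% and 16.0%) and Lat (0% and 10.4%) highest and none at Bcl11b. The same count of 0 held for 22 fibroblast genes (Tagln highest, 0% and 8.68%), 20 erythroid and megakaryocyte genes (Epb42, 0.975% and 2.75%), 26 neuron genes (Cacna1a, 0% and 0.557%) and 24 hepatocyte genes (Ass1, 0% and 1.75%). Of 18 B cell genes, 1 and 2 reached 20%: Blnk (22.7% and 55.0%) and, in replicate 2 only, Cd72 (17.0% and 38.7%). Of 20 neutrophil genes it was Csf3r alone (22.8% and 68.2%), and of 20 dendritic cell genes Bst2 alone, in replicate 2 (0% and 38.9%), a gene that is also in the interferon-stimulated list. In replicate 2 the 5 counts of 0 lay below the random ranges, which began at 1 or 2 genes. The B cell, neutrophil and dendritic cell counts lay inside theirs, of 1 to 7, 1 to 8 and 1 to 9. In replicate 1 all 8 ranges began at 0, so a count of 0 there was no lower than random lists can give. A pair of large gene families was as bare. Of 1134 olfactory receptor genes, 0 and 1 reached 20%, against 56 to 88 and 200 to 251 in random lists, the member being Olfr99 (0% and 22.0%). All 67 histone genes had no peak in either replicate, among them Hist1h1a, but random lists of such short genes held 0 to 3 and 0 to 6.

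**Figure D2:**
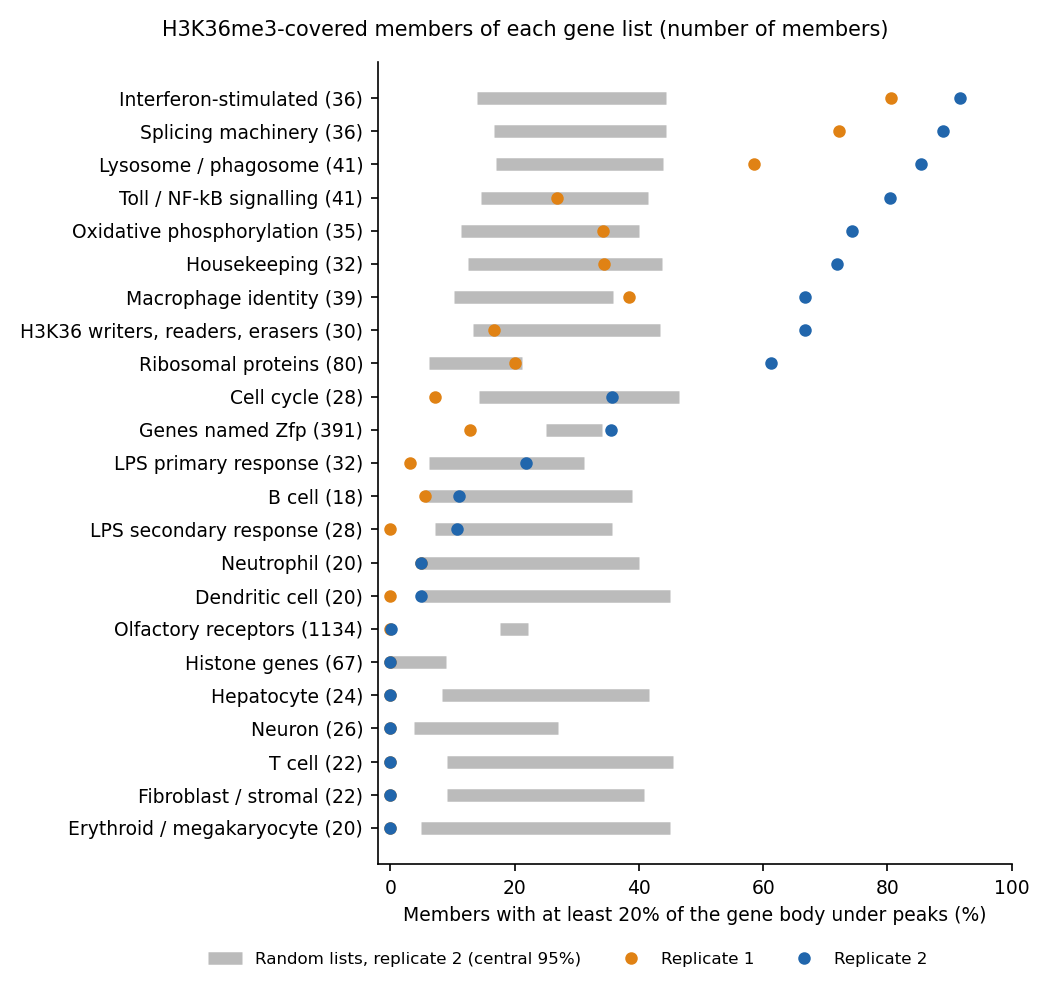
Members of each gene list with at least 20% of the gene body under H3K36me3 peaks, as a percent of the list, in replicate 1 (orange) and replicate 2 (blue), with the number of members in parentheses; grey bars span the central 95% of random lists of matched gene length in replicate 2. Interferon-stimulated genes are highest, with 29 of 36 members in replicate 1 and 33 in replicate 2, and the T cell, fibroblast, erythroid, neuron, hepatocyte and histone lists are at 0.

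Density, as enrichment times covered bases per base of gene body, was ranked among coding genes of at least 5 kb. Zfp110 was highest there with a mean of 6.16 over the replicates (3.89 and 8.44), followed by Zfp263 (3.42 and 7.32), Zfp90 (3.08 and 7.46), Tecpr1 (2.56 and 7.19), Rbak (2.58 and 7.15) and Zfp68 (3.30 and 6.21). The other 4 of the top 10, Slfn8 (2.92 and 6.44), Oas3 (2.86 and 6.46), Rnf213 (3.44 and 5.72) and Helz2 (2.73 and 5.42), are known to be interferon-inducible, but no test of such genes was made on this ranking. Zfp869, at 4393 bp too short to be ranked, had a mean density of 6.86 (5.05 and 8.68). Genes named Zfp were 4 of the top 10 and 8 of the top 100, and 2.07% of all 17798 coding genes of at least 5 kb. Of 391 genes so named, 50 reached 20% in replicate 1 and 139 in replicate 2, with Zfp869 (96.2% and 100%), Zfp110 (76.2% and 90.7%) and Zfp68 (67.7% and 76.4%) highest and Zfp105 and Zfp112 without a peak. Their median covered share, 0.611% and 8.97%, was at the 100th percentile of random lists, while their number at 20% lay at the 91.2th in replicate 1 and at the 99.5th in replicate 2. Among genes with a peak only, a comparison chosen after seeing the data, the median of the 251 Zfp-named genes lay at the 0.175th percentile.

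The X chromosome was almost without widely covered genes, though it held 81 peaks in replicate 1 and 271 in replicate 2. Of 948 X-linked coding genes, 2 reached 20% in replicate 1 (0.211%) and 6 in replicate 2 (0.633%), against 8.06% and 24.6% of 20807 autosomal genes. Eif2s3x, a translation initiation factor gene, was the only X-linked gene marked (27.7% and 56.7%), and the histone demethylase gene Kdm5c was just under the limit in replicate 1 (19.8% and 64.1%). Psmd10 reached 20% in replicate 1 but not in replicate 2 (20.2% and 12.7%), and was picked after its values were seen. Eif2s3x and Kdm5c are known to escape X inactivation in females, as are Kdm6a (7.90% and 11.3%) and, picked after its values were seen, Ddx3x (0% and 10.3%). The 7 Y-linked genes in the list of X inactivation and Y-linked genes, among them Ddx3y and Eif2s3y, had no peak. Of the 11 coding genes in that list, 1 reached 20% in replicate 1 and 2 in replicate 2. Xist, the noncoding RNA that coats the inactive X, had 0% and 9.90% of its length under peaks. Peaks on the X that were called had a median enrichment of 2.98 and 3.42, against 3.22 and 3.89 on autosomes. Neither the sex of the animals nor a copy number of the X is given in the labels.

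**Figure D3:**
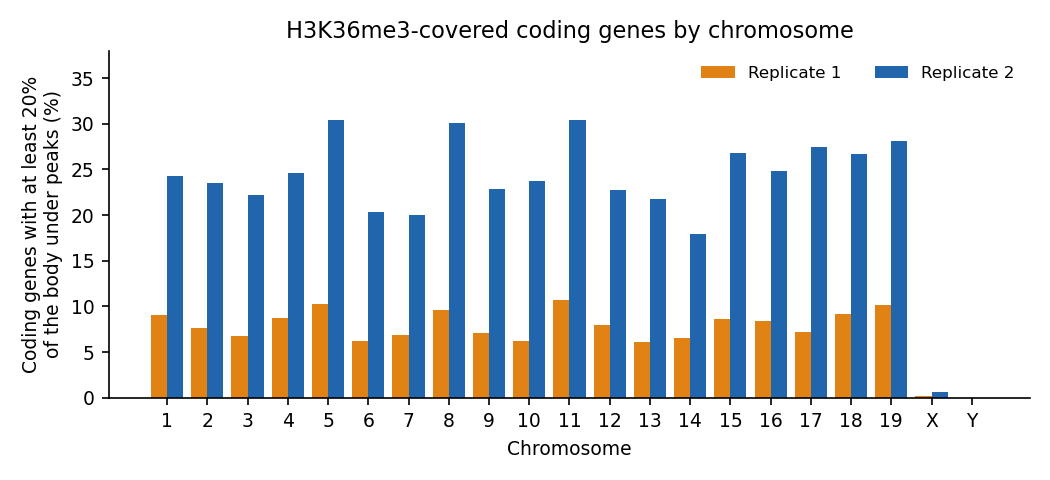
Percent of coding genes on each chromosome with at least 20% of the gene body under H3K36me3 peaks, in replicate 1 (orange bars) and replicate 2 (blue bars). The X stands at 0.211% and 0.633% and the Y at 0%, against 8.06% and 24.6% over the 19 autosomes.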

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

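The alternatives set before the data were examined were a higher peak threshold, other overlap rules, equal list lengths, the authors' combined lists, other marking limits, each replicate alone and other gene sets; restricting genes to those with a peak, leaving out the X and Y, summing overlap, the mean in place of the median and counting members at 20% were chosen only after the results were seen. No paired analysis was possible because there is 1 group. Of 606 alternative values of counts, shares, folds, correlations and list percentiles, 486 stayed within their tolerance, 114 moved beyond it and 6 list percentiles fell below the 95th. The tolerance was 1.5 times either way for counts and covered Mb, less than 0.05 for correlations, the 95% binomial interval for shared peaks, 1 SD of the replicates for folds and the share of bases in genes, and the same side of the 95th for percentiles; any change in the Jaccard index counted as moved. Of the values that stayed, 321 were percentiles, which say little on stability, since most random lists have a median at or near 0 and a covered median then lies at the 100th. Of 810 covered percents of named genes under other settings, 754 stayed within 1 SD of the replicates and 56 moved. Taking 1 replicate alone cannot move such a percent, or the share of bases in genes, beyond 1 SD by construction. That SD also grows with the gap between the replicates, so these counts say little on stability. The excess of peaks in coding genes changed in 1 of 7 alternatives, to 2.12-fold from 2.48 (the mean of the replicates) with all annotated genes, which make up more of the genome. The cause of the other changes was not tested, except where a rule or a list by its construction admits more or fewer peaks or genes.

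Where peaks needed a −log10 q of at least 5, replicate 1 kept 6719 peaks over 8.23 Mb, shared peaks were 87.9% of replicate 1 and 5.55% of replicate 2, the Jaccard index was 11.3%, and 317 genes were marked. The last 10% of marked genes then exceeded the first 66.6-fold, against 24.0-fold for the mean of the replicates, and the correlations were 0.531 (Pearson) and 0.503 (Spearman). Marked members then were 18 of the interferon-stimulated, 12 lysosome, 8 splicing, 5 macrophage identity, 2 housekeeping, 2 Toll-like receptor, 1 oxidative phosphorylation, 3 ribosomal protein and 27 Zfp-named genes. They were 0 in the primary LPS response, H3K36, B cell, neutrophil, cell cycle and X and Y lists. At an enrichment of at least 3, replicate 1 kept 20496 peaks, shared peaks were 85.6% and 12.0%, the Jaccard index was 22.6%, 1067 genes were marked and the correlations were 0.719 and 0.697. Toll-like receptor members fell to 6, and those of the primary LPS response, B cell, neutrophil, cell cycle and X and Y lists to 0. With the replicate 2 list shortened to the 32098 most significant peaks, shared peaks were 68.9% and 21.1% and the Jaccard index 33.0%.

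By the overlap rule, shared peaks were 90.2% of replicate 1 and 40.9% of replicate 2 from 1 bp, 26.0% and 14.3% with 50% of both peaks, and 84.8% and 21.9% with overlap summed over peaks. Over all coding genes the correlations were 0.854 and 0.861, where genes without a peak add ties at 0.

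Marking moved with the list and the limit. In the authors' replicated list 5271 genes were marked and in their pooled list 5507. Members in the replicated list were 23 macrophage identity, 22 housekeeping, 33 Toll-like receptor, 5 primary and 2 secondary LPS response, 30 oxidative phosphorylation, 18 H3K36, 2 B cell, 1 dendritic cell, 12 cell cycle, 3 X and Y, 145 Zfp-named, 1 histone and 47 ribosomal protein genes. From 10% covered, 3332 genes were marked, with 17 housekeeping, 23 Toll-like receptor, 5 primary and 1 secondary LPS response, 22 oxidative phosphorylation, 13 H3K36, 1 T cell, 2 B cell, 6 cell cycle, 2 X and Y, 108 Zfp-named and 23 ribosomal protein members. From 50%, 91 genes were marked, with 9 interferon-stimulated, 4 splicing, 2 Toll-like receptor, 1 lysosome and 6 Zfp-named members, and 0 in the macrophage identity, housekeeping, primary LPS response, oxidative phosphorylation, H3K36, B cell, neutrophil, cell cycle, X and Y and ribosomal protein lists.

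With either replicate alone, the marked genes ranged from 1679 (replicate 1) to 5119 (replicate 2), replicate 2 being higher in each of these ranges. Members ranged from 15 to 26 for macrophage identity, 11 to 23 for housekeeping, 11 to 33 for Toll-like receptor, 1 to 7 for primary and 0 to 3 for secondary LPS response, 12 to 26 for oxidative phosphorylation, 5 to 20 for H3K36, 1 to 2 for B cell, 0 to 1 for dendritic cell, 2 to 10 for cell cycle, 1 to 2 for X and Y, 50 to 139 for Zfp-named, 0 to 1 for olfactory receptor and 16 to 49 for ribosomal protein genes. The ribosomal protein median ranged from the 50th percentile of random lists (replicate 1, where it ties with them at 0) to the 100th, while its count at 20% was at the 100th in each replicate. Without genes that overlap another coding gene, members fell to 12 lysosome, 7 oxidative phosphorylation and 3 H3K36 genes, because fewer genes were counted. Without the X and Y, the X and Y list held 0 marked genes by construction. Among genes with a peak only, the percentile was 85.5 for Toll-like receptor, 89.5 for ribosomal protein and 0.175 for Zfp-named genes. By the number of members at 20% in replicate 1, it was 92.6 for H3K36 and 91.2 for Zfp-named genes. Depth is unknown for both replicates, which leaves a gene without a peak undetected and keeps the difference between the replicates in number of peaks and marked genes from being set against their reads.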

Other observations

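In this part the test on escape genes and both tests on interferon-stimulated genes were chosen only after the results were seen; the other 4 tests were set out after the peaks per chromosome and per replicate were known but before their own results.

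Noncoding genes that overlap no coding gene were rarely covered: 6 of 6028 had at least 20% under peaks in both replicates. AU020206, on chromosome 7 from 75769038 to 75782099, was the most widely covered of those of at least 5 kb, at 54.1% in replicate 1 and 66.0% in replicate 2, followed by the small nucleolar RNA host gene Snhg17 (19.0% and 62.5%). The nuclear RNA gene Neat1 on chromosome 19 (6.11% and 25.5%) also reached 20% in replicate 2 only. These 3 genes were picked after their values were seen.

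Few X-linked genes were widely covered: 6 of 948 coding genes reached 20% in replicate 2, against 24.6% of autosomal ones. A lack of X-linked genes of expressed kinds was argued against, since 0 of 10 X-linked members of the macrophage, housekeeping, signalling, lysosome, oxidative phosphorylation and splicing lists reached 20% in replicate 2 (0%, upper exact 95% bound 30.8%), against 81.6% of 212 autosomal members. A single active X copy would halve the enrichment if the caller's background were genome-wide, which is not known here. Such a copy cannot be told apart from other causes, because the X-to-autosome share of covered bases was 0.747 times the share expected after halving in replicate 2 and 4.87 times in replicate 1. Silencing of 1 of 2 copies in female cells cannot be told apart either. Kdm5c and Eif2s3x, the most widely covered X-linked genes in replicate 2, are known to escape it, but this was seen before a set of 6 escape genes was named, so a test that includes them was prompted by what it measures. That holds for the 4 X-linked members of the list fixed beforehand too, of which 2 reached 20% in replicate 2, against 4 of 944 other genes (one-sided Fisher's exact p = 0.000199), and 1 in replicate 1, against 1 of 944 (p = 0.00843). Of the other 4 of the set, Kdm6a, Ddx3x, Utp14a and Pbdc1, 0 reached 20% in replicate 2, against 4 of 942 other X-linked genes (Fisher's exact p = 1), too few to decide. Xist had 0% of its length under peaks in replicate 1 and 9.90% in replicate 2, and the Y-linked genes listed had no peak in either. The Xist call rests on replicate 2 and a gene without a peak is only undetected, so these values leave the sex open. The sex of the cells is not given in the labels, and mappability and the control were not tested.

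Replicate 2 held more and wider peaks, with 3446 genes at 20% in it alone. Cells of another type in numbers that would cover their markers were argued against, for the types listed here. Of 122 markers of T cells, B cells, neutrophils, dendritic cells, fibroblasts and erythroid cells, 1.64% reached 20% in replicate 2 alone (upper exact 95% bound 5.80%). Among all coding genes 15.7% did, but these include genes of the macrophages themselves, so a lower share of markers does not by itself argue against such cells. The statement rests on the markers being bare: 111 of the 122 had no peak in either replicate. The 4 markers that reached 20% in replicate 2 at all, Blnk, Bst2, Cd72 and Csf3r, are also known from macrophages. A smaller share of such cells, or other cell types, could leave these counts unchanged and was not excluded. Lower detection power in replicate 1 is a candidate explanation: among the 5119 genes at 20% in replicate 2, density in replicate 2 ranked the 1673 also at 20% in replicate 1 above the rest with an area under the curve of 0.893 (medians 2.79 and 1.47). It leaves exceptions: of the 3446 genes at 20% in replicate 2 alone, 174 had a density there above 2.79, the median of those at 20% in both, and 21 of these had no peak in replicate 1, among them Gsdmd (density 4.07) and Tmem128 (4.04). The ranking by density would also arise from any cause that leaves covered shares correlated between the replicates, so it does not favour lower power over other causes. Sequencing depth and the efficiency of the immunoprecipitation were not separated, since read totals were not used here. A biological difference between the cultures was not tested.

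Interferon-stimulated genes were widely covered without stimulation, with 33 of 36 members at 20% in replicate 2. Gene length and base composition were argued against, since the list's median lay at the 100th percentile of random lists matched on both. Secondary LPS response genes showed no such excess: 3 of 28 reached 20% in replicate 2 (10.7%, upper exact 95% bound 28.2%), at the 9.24th percentile of random lists. Among interferon-stimulated genes 91.7% did, but their median length was 15586 bp, against 6624 bp. Exposure to a Toll-like receptor ligand before harvest cannot be decided from this. The series has no stimulated sample to show that secondary response genes gain peaks after a ligand. An exposure too short to leave H3K36me3 was not tested. Basal interferon signalling in the cultures may account for the pattern, but this stays a hypothesis, as the series has no group with that signalling blocked.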
